A study of Mus musculus with 2 samples.

How the data were processed

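The series measured H3K27me3, a repressive histone modification deposited by the Polycomb complex that contains Ezh1 or Ezh2, by chromatin immunoprecipitation and sequencing (ChIP-seq) in the embryonic facial prominence of the mouse, the embryonic tissue from which the face forms, at embryonic day 15.5. Per the labels, the tissue came from strain B6NCrl and pooled embryos of both sexes, 78 embryos for replicate 1 and 62 for replicate 2. The 2 samples are biological replicates of 1 group. There was no treatment and no second tissue, so the comparisons are between replicates, between sets of genes and between regions of the genome.

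Only peak lists were analysed here: 1 list for each replicate, 1 list called on the reads of both replicates (the pooled list) and the part of the pooled list that was kept as replicated (the replicated list). Per the text files deposited with the samples, technical replicates were merged before each replicate's peaks were called, the lists are in narrowPeak format, and replicate 1's peaks were derived from 2 further files and replicate 2's from 1 further file whose content is not described there. The aligner, the peak caller and the criterion for keeping a peak as replicated are not given in the sources used here. The authors' value in column 7 of each list is a fold enrichment, a linear ratio with 1 value per peak. Columns 8 and 9 of the deposited lists hold the −log10 of the p-value and of the q-value of each peak, and the lowest −log10 p was 2.02 in both replicates' lists and 2.03 in the others. The fold enrichment was used here only to describe, rank or filter peaks within a list. Every peak of the replicated list was found in the pooled list with the same coordinates and values.

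The depth of the libraries is unknown, since the lists hold no read counts. Each replicate's own list therefore served as its measurement, and values from the lists are given as the mean and SD over both replicates (n = 2). An SD from 2 values is imprecise. No counting interval was computed for peak values.

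Per the labels, coordinates are in mouse build mm10. They were compared with the GRCm38 assembly, the same primary assembly, and no peak lay past a chromosome end or on unplaced sequence. Genes came from GENCODE release M21. Of 21938 protein-coding gene records on placed chromosomes, 21755 lay on chromosomes with a peak in any list. Chromosome Y had none. After 27 records with repeated symbols were dropped, 21728 genes were tested. Coordinates are 1-based.

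Each gene had 1 transcription start site (TSS), the 5′ end of its gene record. A gene unmarked there can be marked at another of its annotated starts. A gene was called marked where replicated peaks covered at least 25% of the window from 1 kb upstream to 1 kb downstream of its TSS. The share of this window that peaks covered is called window cover. Gene lists were compared with all other protein-coding genes by 2-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 18 lists and a threshold of 0.05. The lists were Hox genes, regulators of facial mesenchyme and cranial neural crest, of the central nervous system, of endoderm and gut, and of heart and posterior mesoderm, genes of skeletal muscle, cartilage and bone, epithelium, neurons, blood and immune cells, endothelium, housekeeping, signalling ligands and their secreted antagonists, germline, pluripotency, Polycomb and H3K27 demethylases, imprinted genes, and the olfactory receptor family. H19 and Meg3 of the imprinted list are not protein-coding and were not tested. Each list was also set against 10000 random lists matched on the decile of the CpG observed/expected ratio of the TSS window (smallest 2-sided p 0.0002). It was also recounted with all marked members whose windows lay in 1 domain as 1 unit. Marked genes outside the list were grouped in the same way, and unmarked genes stayed counted singly. A domain can thus enter only as a marked unit, and the marked share of the other genes falls too. Fisher's exact tests between 4 pairs of lists were adjusted together. Genes are not independent replicates, since neighbours share domains, so p-values over genes measure counting over genes and not the spread between embryos.

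Overlap between the replicates was the share of peaks with at least 50% of their length covered by the other list, and the bp Jaccard index (shared bp over bp in either list). Expected values came from 100 shuffles along the same chromosome, outside assembly gaps (bedtools 2.31.1; smallest one-sided permutation p 0.0099). The same shuffles gave the expected share of peak bp in TSS windows, exons, introns and intergenic sequence. Domains were replicated peaks within 3 kb of each other, merged. Hox paralogues 1 to 4 were compared with 9 to 13 by a 2-sided permutation test with 100000 resamples. The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were run on simulated data. All 200 genes with planted promoter peaks, among 21728, were recovered with 0 others. In addition, 0 of 100 random gene lists passed 0.05. A planted overlap of 59.9% of 81535 peaks was measured as 60.1%. Far fewer genes were planted than the 2828 marked in the data. These runs check the scripts and do not measure how often the real gene list tests call falsely.

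Gene lists, tests and alternatives were fixed before the data were examined. The rule for named genes took from each list up to 4 marked members with the highest window cover averaged over the replicates and up to 3 unmarked members with the lowest, the protein-coding genes whose TSS lay in the 15 widest domains, up to 10 list members marked from 1 replicate's list only, all Polycomb genes, and the 4 Hox clusters. Ties went to the fold of an overlapping peak and then to list order. Genes named outside this rule are said to be so. The alternatives were the pooled list, each replicate's own list, the regions in both replicates' lists, other windows, cover thresholds and transcript starts, a −log10 q of at least 3, the 50% of peaks with the higher fold, and other merging and overlap rules.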

Results

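H3K27me3 was mapped in the embryonic facial prominence at embryonic day 15.5 in 2 biological replicates, pools of 78 and 62 embryos. The list of replicate 1 held 81535 peaks that covered 35.5 Mb, and the list of replicate 2 held 90910 peaks that covered 39.7 Mb. The pooled list held 87598 peaks over 45.5 Mb, and 35811 of them, covering 31.7 Mb, formed the replicated list. Median peak width was 266 bp in both replicates and 496 bp in the replicated list, whose widest peak spanned 39447 bp. Read depth is unknown from these lists.

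The first question was which gene promoters carried the mark in this tissue. Replicated peaks marked 2828 of 21728 protein-coding genes (13.02%). Replicate 1's own peaks marked 2747 genes and replicate 2's marked 2820, a mean of 2783.5 ± 51.6 (SD, n = 2), and 2460 genes were marked from both lists. A further 287 genes were marked from replicate 1 only and 360 from replicate 2 only. Across genes, window cover in the replicates had a Pearson correlation of 0.957 and a Spearman correlation of 0.838, with the reservation that genes are not independent replicates.

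Hox genes, which set position along the body axis, were marked without exception: 39 of 39, with 100% ± 0 of genes marked over the replicates (SD, n = 2; adjusted p = 1.39e-34, Fisher's exact test). Hoxb9, Hoxb13, Hoxa5 and Hoxa10 had 100% window cover in both replicates. These 39 genes lay in only 5 domains, and counted as 5 units the list passed (adjusted p = 5.19e-05, Fisher's exact test). Each of these units is marked by construction, since domains are built from the peaks, so the recount is not an independent check.

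Regulators of the central nervous system came next, with 58 of 59 marked (98.3%; 99.2% ± 1.20 over the replicates, SD, n = 2; adjusted p = 1.21e-49, Fisher's exact test). Olig1, an oligodendrocyte lineage factor, Pax2, a regulator of midbrain and kidney, Neurog1, a proneural factor, and Gsx1, a homeobox gene of the ventral forebrain, had 100% window cover in both replicates. The exception was Neurod6, a neuronal differentiation factor, with 20.0% window cover by replicated peaks. Its window was covered to 46.2% in replicate 1 and 10.4% in replicate 2. Genes of differentiated neurons were marked in 18 of 28 cases (64.3%; 66.1% ± 2.53, SD, n = 2; adjusted p = 8.77e-10, Fisher's exact test). Among them, the neurofilament gene Nefh, the vesicular transporters Slc32a1 and Slc17a7, and the RNA-binding protein gene Elavl3 had full cover in both replicates. Elavl4, Th, which encodes tyrosine hydroxylase, and Map2 had 0% cover in both. These zeros hold for the 5′ end of the gene record, and more genes of this list were marked with any annotated transcript start.

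Regulators of heart and posterior mesoderm were marked in 27 of 30 cases (90.0%; 88.3% ± 2.36, SD, n = 2; adjusted p = 9.03e-21, Fisher's exact test). Uncx, Irx4, Nkx2-3 and T, the brachyury gene of early mesoderm, had 100% window cover in both replicates. The unmarked members were Tbx6, Tbx3 and Msgn1, which had 0% replicated cover. Regulators of endoderm and gut were marked in 20 of 26 cases (76.9%; 73.1% ± 0, SD, n = 2; adjusted p = 4.94e-13, Fisher's exact test). Neurog3 and Insm1, factors of endocrine cells, Ptf1a, a pancreatic factor, and Cdx1, an intestinal factor, had 100% cover in both replicates. Hnf4a, Isx and Creb3l3 had 0%.

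The list of regulators of facial mesenchyme and cranial neural crest, the sampled tissue, was written from general knowledge, and some of its members also act in other tissues. These genes were marked in 38 of 50 cases (76.0%; 80.0% ± 2.83, SD, n = 2; adjusted p = 1.58e-23, Fisher's exact test). Hand1 reached 97.9% ± 2.97 window cover, Foxf1 97.6% ± 3.43, Barx1, a homeobox gene of the jaw primordia, 96.5% ± 0.672, and Sox10, a neural crest factor, 96.5% ± 1.38 (SD, n = 2). Prrx2, a homeobox gene of craniofacial mesenchyme, Eya1, a cofactor of sine oculis homeobox proteins, and Snai2, a factor of neural crest migration, had 0% in both replicates. Nr2f2 differed between the replicates, with 12.2% window cover in replicate 1 and 68.9% in replicate 2.

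Signalling ligands and secreted antagonists were marked in 41 of 54 cases (75.9%; 73.1% ± 1.31, SD, n = 2; adjusted p = 3.34e-25, Fisher's exact test). Wnt7a, Shh, Wnt3a and Fgf15 had 100% cover in both replicates, whereas Wnt5a, Fgf7 and Fgf10 had 0% in both. The replicates differed at Dkk2, with 14.0% in replicate 1 and 47.3% in replicate 2, and at Nog, an antagonist of bone morphogenetic proteins, with 43.6% and 12.6%.

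Epithelial genes were marked in 18 of 34 cases (52.9% ± 0 over the replicates, SD, n = 2; adjusted p = 5.99e-08, Fisher's exact test). Ovol1 had 98.7% ± 1.84 cover, the desmosomal gene Pkp1 96.6% ± 4.84, Krt8, a keratin of simple epithelia, 90.5% ± 2.83, and Grhl3 89.8% ± 6.68 (SD, n = 2). Trp63, a regulator of stratified epithelium, and the basal keratins Krt5 and Krt14 had 0% in both replicates. Endothelial genes were marked in 9 of 20 cases (45.0%; 47.5% ± 3.54, SD, n = 2; adjusted p = 0.00075, Fisher's exact test). Gata2, Sox18, Cldn5 and Flt1 had full cover in both replicates, and the junction genes Pecam1 and Cdh5 and the receptor gene Tek had 0%. Plvap had 10% in replicate 1 and 54.7% in replicate 2.

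Cartilage and bone genes were marked in 11 of 29 cases (37.9%; 36.2% ± 2.44, SD, n = 2; adjusted p = 0.000969, Fisher's exact test). The matrix genes Comp, with 100% ± 0 cover, Acan, with 98.8% ± 1.77, Col9a3, with 87.0% ± 8.24, and Col2a1, with 80.0% ± 5.66 (SD, n = 2), stood against Col9a1, Hapln1 and Col10a1 with 0%. Skeletal muscle genes were marked in 7 of 24 cases (29.2% ± 0, SD, n = 2; adjusted p = 0.0349, Fisher's exact test). The muscle stem cell and determination genes Pax7 and Myod1 had 94.6% ± 2.37 and 100% ± 0 cover, and the contractile and metabolic genes Acta1 and Ckm had 100% ± 0 and 84.9% ± 5.80 (SD, n = 2). Myog, Myh8 and Tnnt1 had 0%. In Fisher's exact tests, the muscle list no longer passed with a window of 2.5 kb either side (adjusted p = 0.128), with at least 50% cover required (0.104), with the stricter q (0.125) or with the higher-fold peaks (0.0586).

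Blood and immune genes were marked in 4 of 28 cases (14.3% ± 0, SD, n = 2), close to the 13.01% of all other genes (adjusted p = 0.825, Fisher's exact test). The 4 were Ikzf1, with 98.4% ± 2.26 cover, Tal1, with 93.8% ± 3.11, Epor, with 57.3% ± 11.7, and Cd3g, with 33.9% ± 4.35 (SD, n = 2). Ptprc, Cd4 and Cd8a had 0%. Pluripotency genes were marked in 9 of 18 cases (50%; 55.6% ± 0 over the replicates, SD, n = 2; adjusted p = 0.000305, Fisher's exact test). Lin28a, Sox2 and Utf1 had full cover and Nr0b1 88.9% ± 1.98 (SD, n = 2), while Zfp42, Dppa3 and Dppa4 had 0%. Imprinted genes were marked in 9 of 25 cases (36.0% ± 0, SD, n = 2; adjusted p = 0.0042, Fisher's exact test). Ascl2, with 100% ± 0 cover, Kcnq1, with 98.2% ± 2.47, and Phlda2, with 82.5% ± 3.71 (SD, n = 2), are neighbours on chromosome 7, as is Cdkn1c, which had 0%. Plagl1 had 87.0% ± 0.460 (SD, n = 2), and Peg3 and Mest had 0%.

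Housekeeping genes were unmarked in 30 of 30 cases, among them Actb, Gapdh and Rplp0, against 13.03% marked among other genes (adjusted p = 0.0345, Fisher's exact test). In Fisher's exact tests, this call ended when marked genes of 1 domain were counted as 1 unit (adjusted p = 0.0526), over regions in both lists (0.0815), with at least 50% cover required (0.0874) and with the higher-fold peaks (0.0552). Germline genes were likewise unmarked in 24 of 24 cases, among them Dazl, Ddx4 and Sycp1, which fell short of the threshold against all genes (adjusted p = 0.0723, Fisher's exact test) and passed against CpG-matched random lists, of which 16.9% of genes were marked (adjusted permutation p = 0.0259). The germline list also passed with the pooled list, any overlap and any transcript start. Olfactory receptor genes were marked in 4 of 1093 cases (0.366%; 0.320% ± 0.0647, SD, n = 2), against 13.7% of other genes (adjusted p = 1.02e-59, Fisher's exact test). The difference was much smaller against CpG-matched random lists, of which 1.98% of genes were marked (adjusted permutation p = 0.0004). The 4 marked receptor genes were Olfr94, Olfr1342, Olfr222 and Olfr95, each with less than full cover, and Olfr1, Olfr10 and Olfr1000 had 0%. None of these 4 was marked from both replicates' own lists: Olfr94 and Olfr1342 were marked from replicate 1 only, and Olfr222 and Olfr95 from replicate 2 only. Over regions in both lists, 0% of the family was marked. Olfr1411 and Olfr1410, unmarked by replicated peaks, were marked from replicate 1 only and replicate 2 only, in that order.

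Genes of the Polycomb machinery and of the H3K27 demethylases were marked in 3 of 28 cases (10.7%; 8.93% ± 2.53, SD, n = 2; adjusted p = 1, Fisher's exact test). The catalytic genes Ezh1 and Ezh2, their partners Eed and Suz12, and the demethylase genes Kdm6a and Kdm6b had 0% cover in both replicates. The 3 marked genes were Pcgf5, with 44.0% ± 17.1 cover, Cbx8, with 22.6% ± 7.85, and Pcgf1, with 18.6% ± 26.2 (SD, n = 2). Their cover by replicated peaks, which decides the call, was 67.7%, 27.7% and 25.05%, in the same order. The last 2 lay just past the 25% threshold. Cbx8 was marked from replicate 1 (28.1%) and not from replicate 2 (17.0%). Pcgf1 was covered in replicate 1 only (37.1%). The share of the list fell to 0% over regions in both lists and to 3.57% with a window of 500 bp either side or 50% cover required. It rose above that of other genes with a window of 2.5 kb either side or any overlap (17.9% each) and with any annotated transcript start (21.4%). No setting passed the threshold (smallest adjusted p 0.121, Fisher's exact test). Phf19 had 11.4% in replicate 1 and 42.6% in replicate 2.

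**Figure D1:**
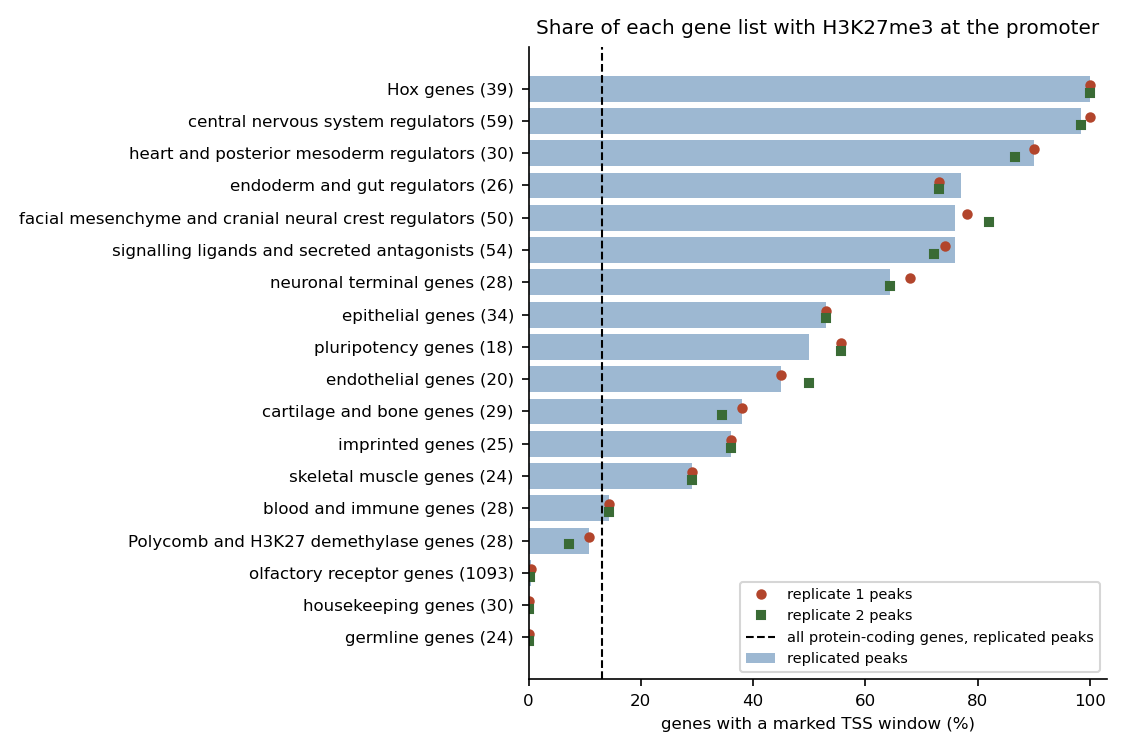
Percent of the genes in each list (number of tested genes in brackets) whose TSS window was covered to at least 25% by replicated peaks (bars), by replicate 1's peaks (circles) and by replicate 2's peaks (squares). The dashed line is the 13.02% of all protein-coding genes; Hox genes (100%) and nervous system regulators (98.3%) lie highest and germline and housekeeping genes (0%) lowest.

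The next comparison asked whether regulators of the sampled tissue carried the mark less often than regulators of other tissues. It compares the fixed lists, whose members are not all specific to 1 tissue and were not shown to be active in this tissue at this stage. The peaks came from bulk tissue, so a marked promoter may carry the mark in only part of the cells. Facial and neural crest regulators were marked less often than nervous system regulators, by 76.0% against 98.3% (adjusted p = 0.000989, Fisher's exact test, odds ratio 0.0546 with a 95% interval of 0.00126 to 0.405). Both replicates' own lists gave the same direction, with 78.0% against 100% in replicate 1 and 82.0% against 98.3% in replicate 2. The difference fell to 86.0% against 98.3% when any annotated transcript start was allowed (adjusted p = 0.0455, Fisher's exact test), and with that choice it did not pass in replicate 2's own list (90.0% against 98.3%, adjusted p = 0.184, Fisher's exact test). Facial regulators were not shown to differ from endoderm and gut regulators (76.0% against 76.9%, a difference whose sign changed between settings, adjusted p = 1; odds ratio 0.95, 95% interval 0.253 to 3.26) or from heart and posterior mesoderm regulators (76.0% against 90.0%, adjusted p = 0.198; odds ratio 0.352, 95% interval 0.0589 to 1.5) by Fisher's exact test. Nervous system regulators were marked more often than the genes of differentiated neurons (98.3% against 64.3%, adjusted p = 0.000114, Fisher's exact test). With any annotated transcript start, 82.1% of the neuronal genes were marked and the difference fell from 34.0 to 16.2 percentage points (adjusted p = 0.0455, Fisher's exact test).

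The 4 Hox clusters were covered almost from end to end. HoxA (chromosome 6, 52155590 to 52260880, mm10) was covered to 96.0% ± 0.511, HoxB on chromosome 11 to 84.6% ± 1.23, HoxC on chromosome 15 to 96.0% ± 0.299 and HoxD on chromosome 2 to 92.2% ± 0.570 (SD, n = 2). Replicated peaks covered 97.2%, 87.4%, 97.7% and 95.9% of these clusters, in the same order. Along the clusters, the 12 anterior genes (paralogues 1 to 4) had a mean window cover of 97.95% and the 16 posterior genes (paralogues 9 to 13) one of 99.3% by replicated peaks. The difference did not pass the permutation test (p = 0.283), and both groups lay close to full cover. The anterior windows are not 12 separate anterior positions. Those of Hoxd3 and Hoxd4 are nearly the same (89.5% each), and the gene record of Hoxa3 starts between the TSSs of Hoxa6 and Hoxa7.

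**Figure D2:**
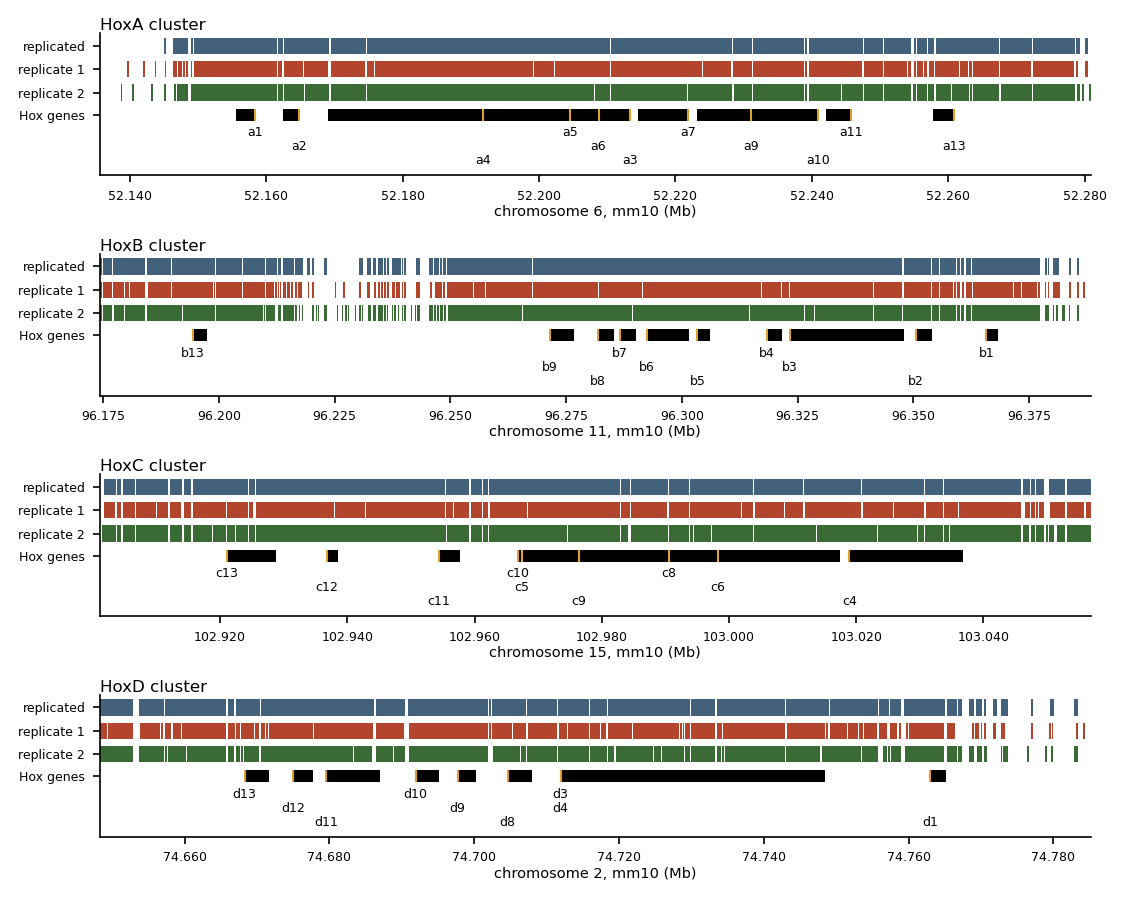
Peaks over the 4 Hox clusters (filled blocks) in the replicated list and in each replicate's list, above the Hox gene records of the annotation (black, with the TSS as a light tick and the gene's letter and number below it), against mm10 position in Mb. Blocks fill nearly all of each cluster, with the main gap between Hoxb13 and Hoxb9 in HoxB, the cluster with the lowest cover (84.6% over the replicates).

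Merging replicated peaks within 3 kb gave 14645 domains with a median width of 0.796 kb. Their number depended on the list, with 31548 from pooled peaks and 34838 to 37508 from a single replicate's list. Of the 14645 domains, 970 were 10 kb or wider, and they held 43.7% of the replicated bp and the TSS of 756 protein-coding genes. The widest was HoxC (chromosome 15, 102887368 to 103077351, 190.0 kb), where replicates' peaks covered 88.0% ± 1.71 (SD, n = 2). It was followed by HoxA with Evx1 (chromosome 6, 52144983 to 52329744, 184.8 kb), Hoxb1 to Hoxb9 (chromosome 11, 96230179 to 96385811, 155.6 kb) and HoxD with Evx2 (chromosome 2, 74639855 to 74773779, 133.9 kb). Another domain held the TSS of the ammonium transporter gene Rhcg (chromosome 7, 79493707 to 79619037, 125.3 kb). One held that of Tbx5, a factor of heart and forelimb (chromosome 5, 119766278 to 119867658, 101.4 kb). Most of these 2 domains lay outside the genes, whose records span 79593363 to 79617657 and 119832668 to 119885219. A further domain held the TSSs of Zic1 and Zic4 (chromosome 9, 91346139 to 91422661, 76.5 kb). Hoxb13 (80.9 kb), Nkx2-3 (65.3 kb) and Neurod2 with Ppp1r1b (62.8 kb) lay in the remaining domains with a protein-coding TSS among the widest 15. The number of domains of 10 kb or more depended on the merging distance, from 104 at 0 bp to 1297 at 5 kb, and on the list, with 1957 from pooled peaks.

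Promoter marking varied with CpG content. In the decile of lowest CpG observed/expected ratio, 0.828% of genes were marked (0.897% ± 0.163 over the replicates, SD, n = 2). The share was highest in the 5th decile, at 24.8% (24.6% ± 0.488, SD, n = 2), and was 10.03% in the 10th (9.78% ± 0.0325, SD, n = 2). The median ratio was 0.552 in marked and 0.453 in unmarked genes.

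**Figure D3:**
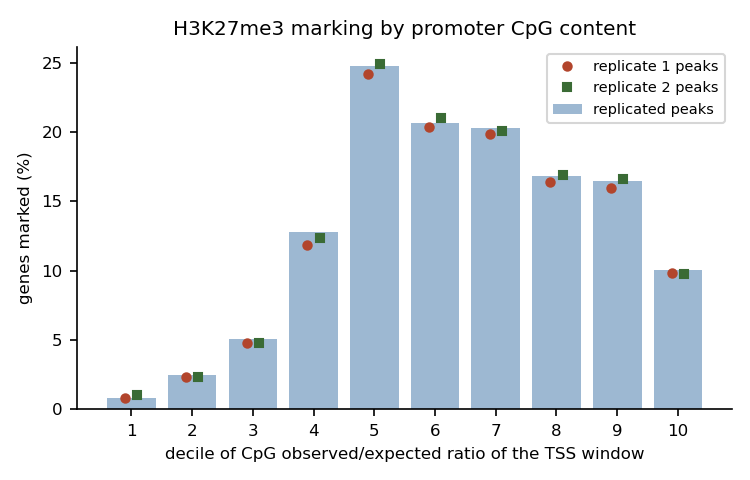
Percent of genes marked in each decile of the CpG observed/expected ratio of the TSS window, from replicated peaks (bars), replicate 1 (circles) and replicate 2 (squares). The share rises from 0.828% in decile 1 to 24.8% in decile 5 and declines to 10.03% in decile 10.

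TSS windows of protein-coding genes held 13.7% of replicated bp, 7.97 times the 1.72% ± 0.0789 of shuffled peaks (SD over 100 shuffles; one-sided permutation p = 0.0099, the smallest these shuffles can give). Exons outside these windows held 8.93% against 3.56% in shuffles. Introns held 33.9% against 36.9% and intergenic sequence 43.4% against 57.8%, both lower than in each of the 100 shuffles. These shares add up to 100%, so the higher shares of TSS windows and exons lower the others. Over the replicates, TSS windows held 11.1% ± 0.611 of peak bp (SD, n = 2).

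By chromosome, replicated peaks covered most sequence on chromosome 11 (22.0 kb per Mb) and on chromosome 19 (21.2 kb per Mb), and least on chromosome 16 (5.87 kb per Mb) among those with peaks. Chromosome Y had no peaks. The X chromosome had 13.1 kb per Mb, a ratio of 1.07 to the autosomes. In the replicates' own lists this ratio was 1.31 ± 0.0033 (SD, n = 2) and in the pooled list 1.44. For replicated peaks it turned below 1 with the stricter q (0.931) and with the higher-fold peaks (0.705). Over regions in both replicates' lists it was 0.713.

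**Figure D4:**
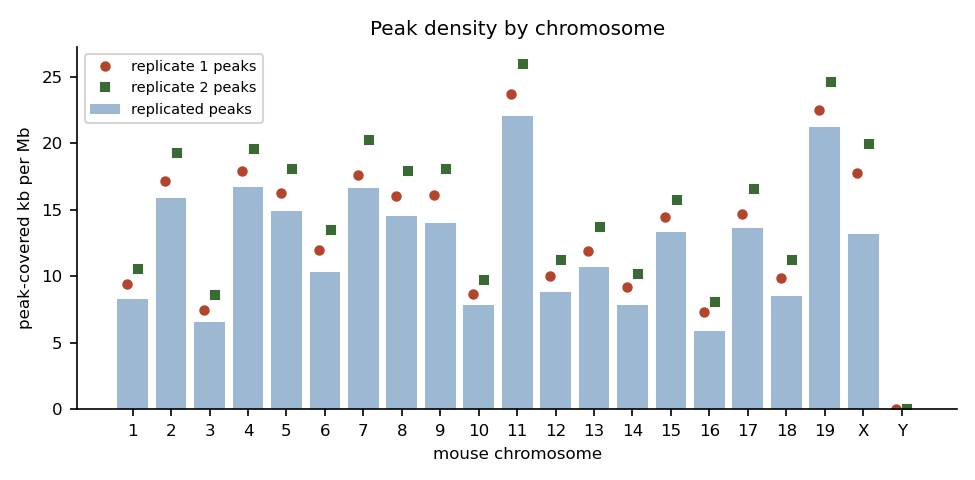
Sequence covered by peaks, in kb per Mb of chromosome outside assembly gaps, for replicated peaks (bars), replicate 1 (circles) and replicate 2 (squares). Chromosomes 11 and 19 have the highest bars (22.0 and 21.2), and the X chromosome shows a wide gap between the bar (13.1) and both replicates (17.8 and 19.9).

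At the level of peaks the replicates overlapped far above chance but in part. Of replicate 1's peaks, 35.9% had at least 50% of their length covered by replicate 2's, against 1.56% in shuffles, and of replicate 2's peaks 29.8% were covered by replicate 1's, against 1.45% (one-sided permutation p = 0.0099 for each, the smallest these shuffles can give). These are the 2 directions of 1 comparison, so they carry no SD. The bp Jaccard index was 35.1% against 0.812%. Sharing went with the authors' fold enrichment. In the highest fold quartile 69.3% of replicate 1's peaks and 60.2% of replicate 2's were shared, and in the lowest 19.3% and 14.8%. No peak had the same coordinates in both lists.

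Pooled peaks kept as replicated were wider and more enriched than those that were not, with a median width of 496 bp against 241 bp and a median fold of 2.70 against 2.23. They were 40.9% of the pooled peaks and held 69.6% of the bp. Of the replicated peaks, 90.2% overlapped a peak of replicate 1 and 91.3% a peak of replicate 2 by at least 1 bp. The share of pooled peaks kept rose to 73.0% at the stricter q and to 67.1% among the higher-fold peaks.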

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

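Read depth, which limits how many weak peaks a list can hold, is unknown here, so depth and threshold effects could not be separated. Of 361 values of comparisons under the alternatives, 308 kept their direction and their side of the threshold or stayed within the tolerance set for them. This held for 215 of 234 gene list values and 37 of 44 values for pairs of regulator lists. All alternatives were chosen before the data were examined. Where a value moved, the cause was not tested, unless it is stated. The number of marked genes ranged from 2184 (50% cover required) to 3585 (any overlap), and 2200 of the 2828 remained marked over regions in both replicates' lists. Overlap between the replicates stayed above each of the 100 shuffles under every alternative run, with 20.0% to 53.2% of peaks shared. The facial against nervous system difference passed under all 11 alternatives, with adjusted p from 0.000116 to 0.0455. The other lists not named here kept their calls.

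Facial minus endoderm regulators, not past the threshold in any setting, turned positive with the pooled list (3.08 points), a window of 500 bp (1.08) or 2.5 kb (5.08), any overlap (9.08) and any transcript start (9.08), and ranged from 4.92 to 8.92 points with 1 replicate left out. The muscle list lost its call with a 2.5 kb window, the stricter q and the higher-fold peaks (25% marked in each) and with 50% cover required (20.8%). The housekeeping list, at 0% throughout, lost it over regions in both lists (adjusted p 0.0815), with 50% cover (0.0874), with the higher-fold peaks (0.0552) and counted by domain (0.0526). The germline list, also 0% throughout, passed with the pooled list (0.0446), any overlap (0.0272), any transcript start (0.0457) and CpG-matched lists (0.0259). The blood list, not called, fell below the other genes with a 2.5 kb window, the stricter q and the higher-fold peaks (10.7% each) and with any transcript start (14.3%). The Polycomb list, not called (10.7%), rose above them with a 2.5 kb window and any overlap (17.9% each) and any transcript start (21.4%), and fell to 0% over regions in both lists, to 3.57% with a 500 bp window or 50% cover, and to 7.14% with the higher-fold peaks or without replicate 1.

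Cover of the 4 Hox clusters together was 93.6%, 88.3% over regions in both lists, and 90.7% to 91.7% with 1 replicate left out. The share of pooled peaks in the replicated list was 73.0% at the stricter q and 67.1% among higher-fold peaks. Domains numbered 35811 without merging, 31548 from pooled peaks, 8472 from higher-fold peaks and 34838 to 37508 from a single replicate's list. Domains of 10 kb or more numbered 104 at 0 bp, 572 at 1 kb, 1957 from pooled peaks, 606 from higher-fold peaks and 1427 to 1639 from a single replicate's list. The X to autosome ratio of replicated peaks, 1.07, fell below 1 at the stricter q (0.931) and among their higher-fold peaks (0.705). It was 1.44 in the pooled list, 1.306 to 1.311 with 1 replicate left out and 0.713 over regions in both lists. The share of marked genes in the lowest 3 CpG deciles, 6.44%, was 7.89% from pooled peaks, 4.27% over regions in both lists, 8.79% with any overlap, 4.76% with 50% cover and 6.24% to 6.26% with 1 replicate left out. Among 186 named genes, 1981 of 2046 values kept the call of marked or unmarked, 46 lost the mark and 19 gained it.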

Other observations

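The gene families in this part, the test of weak peaks by fold quartile, and the genes named here outside the rule (members of these families, Sox1, Pkdcc, Pja1, Casz1, Tfap2b, Meis1, Osr1, Meis2 and Tbx22) were chosen after the data were seen. Several transcription factor families were marked in every member: LIM homeobox factors in 12 of 12 cases, Nkx factors in 14 of 14, Pax factors in 9 of 9, Irx factors in 6 of 6, Dlx factors in 6 of 6 and Zic factors in 5 of 5. All the LIM homeobox and Dlx factors, most Pax factors and some of the others are on the fixed lists, so these counts in part repeat the list results. Other families were split. Forkhead factors were marked in 27 of 44 cases, with Foxg1 and Foxa1 marked and Foxo3 and Foxk2 unmarked. Sox factors were marked in 12 of 19, with Sox17 and Sox21 marked and Sox4, Sox9, Sox11 and Sox12 unmarked. T-box factors were marked in 11 of 17, Gata factors in 5 of 6 and sine oculis homeobox factors in 4 of 6. Each of these 11 families passed Fisher's exact test against other genes after adjustment over 35 families (largest adjusted p 0.00503). The reservations are that neighbours in 1 domain count separately and that members on the fixed lists were counted there already. Klf factors, with 3 of 17 marked, were not shown to differ from other genes (adjusted p = 0.523, Fisher's exact test). Neither were protocadherins (7 of 68), ephrins (0 of 8), semaphorins (5 of 20), keratins (3 of 49), cytochromes P450 (7 of 100) and proteasome subunits (4 of 48; smallest adjusted p of these families 0.0897, Fisher's exact test). Zinc finger proteins named Zfp went the other way, with 14 of 394 marked (3.55%, adjusted p = 1.02e-09, Fisher's exact test).

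Potassium channel genes were marked in 60 of 94 cases (63.8%; 64.9% ± 3.01, SD, n = 2; adjusted p = 6.86e-29, Fisher's exact test), including Kcnj9 and Kcnc2. Calcium channel genes were marked in 12 of 26 cases, sodium channel genes in 6 of 14 and GABA receptor genes in 8 of 19 (largest adjusted p of these 3 families 0.0074, Fisher's exact test). Somatostatin receptors were marked in 5 of 5, adrenergic receptors in 7 of 9, serotonin receptors in 9 of 14 and dopamine receptors in 4 of 5, with Drd3 unmarked (largest adjusted p of these 4 families 0.00204, Fisher's exact test). Histone genes (0 of 67), vomeronasal receptors (0 of 328) and ribosomal protein genes (1 of 79) were marked less often than other genes (adjusted p 0.000297, 2.63e-19 and 0.000553, Fisher's exact test). None of the family tests in this part was matched on CpG content. For olfactory receptor genes, such matching lowered the expected share from 13.7% to 1.98%, so CpG content may carry part of the family differences. Collagens were marked in 18 of 44 cases and claudins in 8 of 23 (adjusted p 1.34e-05 and 0.00814, Fisher's exact test). Of 9598 non-coding RNA gene records, 778 were marked (8.11%). Of the 15 widest domains, 5 held no protein-coding TSS. One lay 52.3 kb from Pax2 (chromosome 19, 44626160 to 44703733), one 49.0 kb from Sox1 (chromosome 8, 12444267 to 12509830), one 76.1 kb from Pkdcc (chromosome 17, 83064916 to 83139203), one 73.1 kb from Pja1 (X chromosome, 99544404 to 99615028) and one overlapped Casz1 (chromosome 4, 148841028 to 148907942). Replicates' peaks covered only 39.7% ± 0.220 of the domain near Pja1 (SD, n = 2), and means of 57.7% to 68.1% of the others.

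The density of peaks on the X chromosome was 1.31 times that of the autosomes in each replicate's list and 0.713 times over regions in both lists. Noise near the calling threshold stays open as an explanation of the excess. Of replicate 1's X peaks 27.2% were shared with replicate 2, against at most 2.16% in 100 shuffles along X. This planned test took in strong X peaks too, which put it above shuffles whatever the weak calls are. In the replicated list the ratio was 1.07, and it was 0.931 at the stricter q and 0.705 among higher-fold peaks. These filters were not applied to a replicate's own list, so they do not show whether its excess lies in weak calls. X peaks were shared less than autosomal peaks within the same fold quartiles, by -8.32 percentage points, beyond the lowest autosome at -3.79. This is a mean over all fold quartiles, the highest included, so it does not single out weak calls. Whether weak X calls that recur less account for part of the excess stays open. A silent X chromosome in the female embryos of the pools is another candidate explanation, which the data did not decide: 5 genes that escape X inactivation had 0% body cover by pooled peaks, but 546 of 948 X genes did too, and the permutation p of 0.0596 was the smallest this test can give. The pools mix the sexes, so sex could not be compared.

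Fewer than 36% of peaks were shared between replicates, while 2460 genes were marked from both. Whether weak calls are only noise was not decided by the lowest fold quartile, of which at least 14.8% was shared, against at most 1.71% in shuffles of the whole list. The shuffles spread peaks over whole chromosomes, so calls placed at random within the regions common to both lists could exceed them too. A part of the calls may be noise: 24.4% of replicate 1's peaks and 25.1% of replicate 2's had a q above 0.05, and at the stricter q the shares shared rose to 53.2% and 45.2%. Whether sharing was by broad regions alone was not decided. Moving replicate 2's peaks by 10 kb lowered the share for replicate 1 from 35.9% to 11.8%. The 14645 domains of replicated peaks had a median width of 0.796 kb, and only 970 were 10 kb or wider. Such a move takes peaks out of most domains, so a fall would follow from sharing by position or by region. Moves by 1 kb and 3 kb left 24.6% and 19.2%, and the value after 10 kb stayed above shuffled peaks (1.56%), so part of the sharing may still be regional. One candidate explanation is that a domain was called as separate pieces in the lists: 65.1% of unshared peaks, averaged over both directions, lay within 3 kb of a peak of the other replicate, and 23.5% of replicate 1's did in 20 shuffles. Joining peaks within 1 kb raised the bp Jaccard index from 35.1% to 42.2% but lowered the share of peaks shared to 25.2% and 20.0%, so how far separate pieces account for the unshared peaks stays open.

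Facial regulators were marked less often than nervous system regulators, by -22.3 percentage points. CpG content of the promoters was argued against as the whole cause, since permuting membership within CpG deciles gave p = 0.0002 (10000 permutations). The use of 1 transcript start per gene may carry part of it: with any annotated start the difference was -12.3 points (adjusted p = 0.0455, Fisher's exact test), passed with replicate 1's list (0.0157) and missed with replicate 2's (0.184), and Tfap2b, Meis1, Osr1, Meis2 and Tbx22 became marked. No biological explanation was tested, since the series has 1 tissue and the lists hold no expression values.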
